A study of Mus musculus with 14 samples.

How the data were processed

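RNA from 14 samples of FDCPmix cells was measured on Agilent single-colour (Cy3) mouse gene expression arrays, 4 to a slide at most. Per the labels, cells from maintenance culture were stained, sorted by flow cytometry, lysed for RNA and labelled with a low-input single-colour kit. The samples fall into 5 groups by the labels: Kit+Gr1-Sca1hi (3), Kit+Gr1-Sca1lo (3), Kit-Gr1- (3), Gr1+ (3) and unfractionated (2). The array positions in the deposited files place them on 4 slides. Slide 1 held replicate 1 of the 4 sorted fractions. Slide 2 held replicate 2 of Sca1lo, Kit-Gr1- and Gr1+ with unfractionated replicate 1. Slide 3 held Sca1hi replicate 2, replicate 3 of Kit-Gr1- and Gr1+, and unfractionated replicate 2. Slide 4 held replicate 3 of Sca1hi and Sca1lo.

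Per the file headers, the scans were read with Agilent Feature Extraction 10.1.1.1 under a single-colour protocol, and the deposited scanner files give each spot's intensity as a processed signal that was background-subtracted and detrended within the array. They also hold the unprocessed median intensity of the spot and of its local background, as deposited. The deposited series matrix holds log2 values, and each was checked to equal the log2 of the processed signal of the same spot, with a largest difference of 5e-09. The series matrix is therefore neither scaled between arrays nor centred, and its column medians run from 6.82 (unfractionated replicate 2) to 12.3 (unfractionated replicate 1). The processed intensities were used for the main results and the series matrix as an alternative.

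Control spots were set aside, leaving 43379 spots of 41174 probes per array. The files pair probes with transcript accessions, and a table of mouse genes on assembly GRCm38.p6 gave symbols to 23374 probes (16535 symbols). The other 17800 probes kept their accession or array name. The headers name build mm8 for the array, so the table was used for names alone and no coordinates are given. Spots of the same probe were averaged. The log2 processed signal was scaled by subtracting each array's 75th percentile, and a probe was kept when its spots were well above background on at least 3 of the 14 arrays, whatever their group. This kept 40295 probes, and the kept probe with the highest mean over all arrays stood for its gene, giving 32476 genes, 16462 of them with a symbol.

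All 14 arrays entered 1 fit in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a trend on the mean signal), with 5 groups and no covariates, leaving 9 residual degrees of freedom and a prior of 3.95. The Kit-Gr1-, Gr1+ and unfractionated groups were each compared with the mean of both Kit+Gr1- groups, then Kit-Gr1- with Gr1+, Sca1hi with Sca1lo, and unfractionated cells with Kit-Gr1- and with Gr1+. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Differences are log2 values of the first group minus the second. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

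Before the data were examined, 26 lists of genes, the comparisons, the test, the alternatives (bar those named further on) and the rule for naming genes were written down. The lists cover erythroid regulators, red cell genes, platelet genes, primary and secondary granule genes, myeloid regulators, monocyte, eosinophil, mast cell and basophil, lymphoid and antigen presentation genes, stem and progenitor genes, cytokine receptors, cell cycle, metabolic and stress programmes, and the gate markers. Of the gate markers 3 were measured (Kit, Ly6a and Ly6c1), and they were reported singly. The other 25 lists were tested in the 4 comparisons of sorted fractions by camera, which compares a list with all other genes, with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes moved one way on balance, were run beside it. Adjustment was over the 25 lists within a comparison, and members were also adjusted over the list alone. Some genes stand in more than 1 list, such as Kit, Epor, Gfi1 and Csf3r.

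Genes were named by a fixed rule. In each comparison of sorted fractions these were the 10 largest increases and the 10 largest decreases among called genes with a symbol, whose probe was well above background on every array of the higher group and whose arrays did not overlap. The gate markers and the regulators Gata1, Klf1, Gata2, Spi1, Cebpa and Ddit3 fell under the rule in every comparison, though not all of their values are given here. From each list up to 4 called members with the largest change were named, or where none was called up to 2 as values. For unfractionated cells the limit was 5 each way. A fold against a group that was not above background was computed against the background as a lower bound.

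The genes called between Kit-Gr1- and Gr1+ cells were tested as 2 further lists between Sca1hi and Sca1lo cells. Changes shared by the Kit-Gr1- and Gr1+ fractions were counted, and the correlation of both sets of changes was set beside 20 simulated draws with no effect and the same shared arrays. A further 20 draws, chosen after seeing the data, kept the deviations of equal replicate numbers together.

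The fit was tested on simulated data built on the observed spread, with known changes in 67, 67 and 66 of 32476 genes. For Kit-Gr1- against Kit+Gr1- cells it called 5.97%, 43.3% and 62.1% of the genes changed by 1, 2 and 3 on the log2 scale, and for Gr1+ against Kit+Gr1- cells 10.4%, 28.4% and 53.0%. For Kit-Gr1- against Gr1+ cells the shares were 1.49%, 29.9% and 51.5%, and for Sca1hi against Sca1lo cells 7.46%, 26.9% and 53.0%. Unchanged genes were called 1, 9, 0 and 7 times. The simulation took the arrays' deviations as independent, while arrays of equal number deviated together in part, as given next. These shares and counts may therefore not carry over to the real arrays.

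Whether equal replicate numbers pair the samples was checked by correlating each array's deviations from its group mean across genes. Between Sca1hi and Sca1lo they were 0.66, 0.68 and 0.82 for equal numbers, between Sca1hi and Gr1+ 0.75, 0.73 and 0.85, and between Sca1lo and Gr1+ 0.60, 0.66 and 0.78. Arrays of equal number also share a slide or compressed signals in part, and the labels state no pairing, so the fit behind the main values carries no block.

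Alternatives changed 1 choice at a time: background correction (normexp with an offset of 50, on the spot's median signal since the deposited files carry no mean signal), scaling by array medians or quantiles, the filter on dim probes, the mean of a gene's probes, slide or replicate number as a block, the arrays in the fit, array weights, the eBayes trend, the minimum fold, the series matrix values, the comparator and each array left out in turn. Fits without unfractionated replicate 1 as the doubted array, and without the 4 arrays with compressed signals, were chosen after seeing the data. No array was left out of the main values. Spots that the scanner software had marked as uneven or as outliers among their copies, between 69 and 493 per array, were left out where the probe had another spot. The precision is that of 2 or 3 arrays per group. The spread of each gene is pooled over all 5 groups, the unfractionated pair included.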

Results

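FDCPmix is a mouse blood progenitor line, of bone marrow origin per the labels, that grows with interleukin-3 and can give rise to several blood lineages. Cells from maintenance cultures were sorted by surface Kit, the receptor for stem cell factor, by Gr1, an antigen of granulocytes carried by the Ly6g and Ly6c proteins, and by Sca1, the product of Ly6a. RNA was measured on 14 single-colour oligonucleotide arrays: 3 of Kit+Gr1-Sca1hi cells, 3 of Kit+Gr1-Sca1lo cells, 3 of Kit-Gr1- cells, 3 of Gr1+ cells and 2 of unfractionated cells. The replicates are biological per the series' design text. Since the labels define the fractions by surface markers, the comparisons ask which genes differ between cells of different surface phenotype within 1 kind of culture. Errors after ± are standard errors from limma unless SD is written, and a gene is said to rise or fall when its adjusted p was under 0.05 and its change at least 2-fold.

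Each array carried 41174 probes on 43379 spots, and between 79.5% of spots (Sca1hi replicate 2) and 99.5% (unfractionated replicate 1) were well above background. The median processed signal lay between 122 and 253 scanner units on 10 arrays. It was 294 on Gr1+ replicate 3, 330 on Sca1lo replicate 3, 801 on Sca1hi replicate 3 and 5180 on unfractionated replicate 1. On these 4 arrays the log2 signals were also compressed, with interquartile ranges of 1.78 to 3.42 against 4.17 to 4.92 on the other 10, so gene counts are given with and without them. The filter on dim probes left 29240 genes without these 4 arrays, against 32476 with them. The number of arrays limits the precision of every value. So does the spread, which is pooled over all 5 groups. The unfractionated pair, which correlated at 0.509, thus enters the standard errors of comparisons that do not use it. Without unfractionated replicate 1 more genes were called between Kit-Gr1-, Gr1+ and Kit+Gr1- cells, as given further on.

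**Figure D1:**
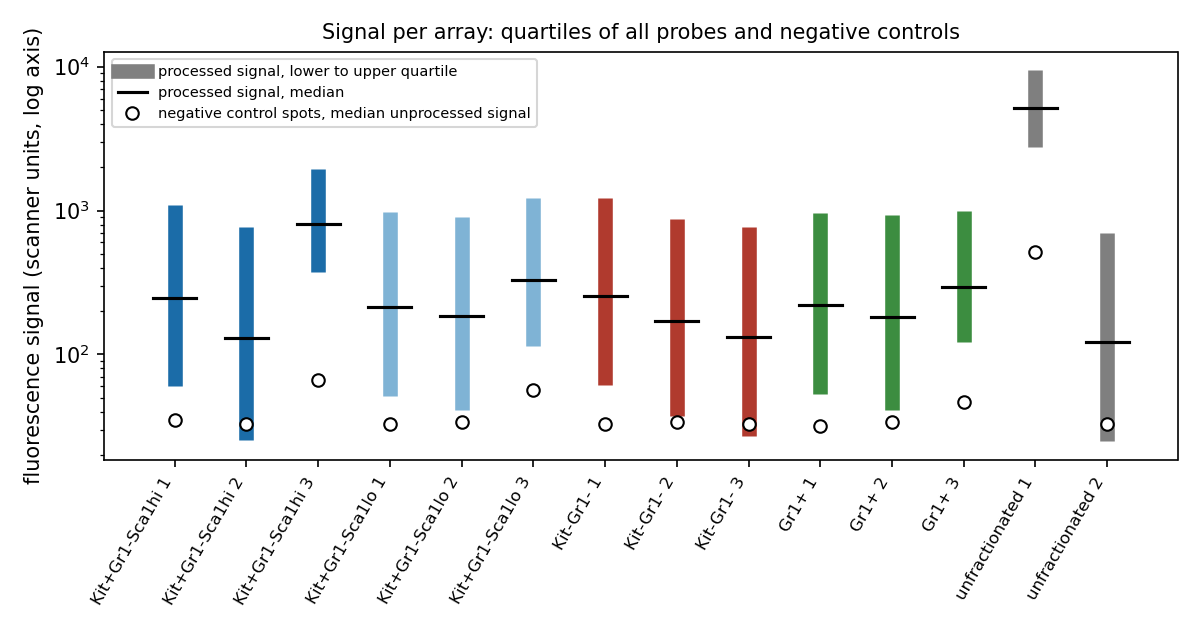
Processed signal of each of the 14 arrays (log axis, scanner units): bars span the lower to the upper quartile, the line is the median and the open circle is the median unprocessed signal of the negative control spots. Unfractionated replicate 1 stands apart, with a median of 5180 and negative controls at 515, against negative controls of 32 to 35 on the 10 arrays with wide signals.

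The Kit-Gr1- fraction carried more RNA of red cell genes than both Kit+Gr1- fractions together (3 against 6 arrays). Aqp1, which encodes a water channel of the red cell membrane, was higher by 4.74 ± 0.48 on the log2 scale (26.7-fold, adjusted p = 0.00346), and the alpha globin gene Hba-a1 by 3.91 ± 0.44 (15-fold, adjusted p = 0.00381). Kel, which encodes the Kell blood group antigen, rose by 3.49 ± 0.33 (11.2-fold, adjusted p = 0.00285), and Epor, the erythropoietin receptor, by 2.59 ± 0.30 (6.03-fold, adjusted p = 0.00432). Gata1, a transcription factor of red cell and megakaryocyte genes, rose by 2.09 ± 0.23 (4.26-fold, adjusted p = 0.00381), and Gp1ba, the platelet receptor for von Willebrand factor, by 1.97 ± 0.25 (3.91-fold, adjusted p = 0.00816). Art4, which carries the Dombrock blood group, rose by 3.14, Ces2g, a carboxylesterase, by 2.95, and Samd14, an adaptor that acts in Kit signalling, by 2.80. Mrvi1, an inositol trisphosphate receptor partner found in platelets, rose by 2.74, and its probes ranged from 1.30 to 2.74.

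Few genes fell in the Kit-Gr1- fraction. Kit mRNA fell by 2.20 ± 0.26 on the log2 scale (4.59-fold, adjusted p = 0.00432), in the direction of the gate, with -2.28, -2.19 and -2.61 within slides 1, 2 and 3. Slide 1 held both Kit+Gr1- fractions, slide 2 Sca1lo alone and slide 3 Sca1hi alone, so values within slides against Kit+Gr1- cells rest on different comparators and do not repeat 1 contrast. Spsb4, an adaptor of a ubiquitin ligase, fell by 2.06 ± 0.31, Thsd1, a membrane protein with a thrombospondin domain, by 1.83 ± 0.29, and Deptor, an inhibitor of mTOR, by 1.45 ± 0.23. Among regulators, the erythroid factor Klf1 was 3.04 ± 0.77 higher and did not pass (adjusted p = 0.533). Its 3 Sca1hi arrays varied widely, with a group mean of -2.12 ± 2.42 (SD) relative to the array's 75th percentile, and without the 4 compressed arrays Klf1 passed. Gata2, a progenitor and mast cell factor, measured 0.80 ± 0.60 and the stress gene Ddit3 0.38 ± 0.30. The myeloid factors Spi1 and Cebpa measured -0.33 ± 0.25 and -0.07 ± 0.65, and Ly6a, which encodes Sca1, -1.21 ± 0.44 with slide as a block. None of these 5 passed. Ly6a measured 0.13 within slide 2 (against Sca1lo) and -2.28 within slide 3 (against Sca1hi).

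As groups, red cell and platelet genes were higher in the Kit-Gr1- fraction. Of 48 tested genes for haemoglobin, haem and the red cell membrane, 3 rose (Aqp1, Hba-a1 and Kel) and 45 did not pass, while 10 rose when adjusted over the list alone. Their median was 0.77 (camera adjusted p = 1.8e-38, and adjusted p = 0.000188 with an estimated correlation), with 0.82, 0.41 and 0.68 within slides 1, 2 and 3 and 0.66 with slide as a block. Of 20 erythroid regulators, 2 rose (Gata1 and Epor) and 18 did not pass, and 3 rose adjusted over the list alone. Their median was 0.39 (camera adjusted p = 3.6e-17, and adjusted p = 0.00106 with an estimated correlation), with 0.45, 0.32 and 0.18 within slides and 0.34 with the block. Of 26 megakaryocyte and platelet genes, Gp1ba alone rose and 25 did not pass, and 6 rose adjusted over the list alone. Their median was 0.80 (camera adjusted p = 3.7e-24, and adjusted p = 0.00137 with an estimated correlation), with 0.97, 0.56 and 0.76 within slides and 0.69 with the block.

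Other groups moved with less certainty, against a median of all genes of -0.25 that became 0.07 with array medians and 0.01 with quantile normalization. Of 48 stem and progenitor genes, Kit alone fell and 47 did not pass, and 1 rose and 3 fell adjusted over the list alone. Their median was -0.28 (camera adjusted p = 0.012, adjusted p = 0.0817 with an estimated correlation) and turned to 0.04 with array medians. Fry called 3 lists higher and 1 lower in this comparison. With replicate number as a block fry called the stem and progenitor list lower (fry adjusted p = 0.00974), but not with slide as a block (fry adjusted p = 0.115). The 35 mast cell and basophil genes had a median of 0.67 (camera adjusted p = 1.6e-11, adjusted p = 0.103 with an estimated correlation), and their largest values, 2.54 ± 0.89 for the basophil protease Mcpt8 and 2.19 ± 0.80 for the receptor Cd200r3, did not pass. Lymphoid genes had a median of -0.48 (camera adjusted p = 0.00434, adjusted p = 0.604 with an estimated correlation) that moved to -0.08 with the slide block, where the call ended. Camera with the preset correlation also placed cell cycle exit (median 0.39), cholesterol synthesis (0.35), p53 targets (0.33) and stress of the endoplasmic reticulum (0.30) above other genes. It did the same for oxidative phosphorylation (0.25), glycolysis (0.23) and ribosome biogenesis (0.09), whose medians with the slide block were 0.04, 0.00 and -0.07 and not called. None of these 7 was called with an estimated correlation, at adjusted p = 0.114 to adjusted p = 0.740 with an estimated correlation. The remaining 12 lists were not called, with medians from -0.43 (eosinophil) to 0.12 (heat shock). For 8 of them, both granule lists and the DNA replication list among them, the median was negative while camera placed the list above other genes. Camera with the preset correlation called DNA replication and mitosis lower with slide as a block (-0.24 and -0.23), though not with an estimated correlation (adjusted p = 0.751 for both). With the preset correlation it also called both lower with quantile normalization, in the deposited series values and without the 4 compressed arrays, and both higher without Sca1hi replicate 2.

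Limma called 21 of 32476 genes in this comparison, 17 higher and 4 lower, of which 10 and 4 had a gene symbol. At an unadjusted p under 0.05 there were 654 genes, against 1624 that chance gives, so the absence of a call does not show an unchanged gene. All 21 had the same sign within slides 1, 2 and 3, which the choice of these genes on the same arrays largely fixes. With slide as a block 21 genes were called (17 higher, 4 lower), though Thsd1 was not among them. Without the 4 compressed arrays 130 genes were called (94 higher, 36 lower), the 21 among them. Without Kit-Gr1- replicate 1 or replicate 3 limma called 0 genes (434 and 407 at an unadjusted p under 0.05), and 0 against Sca1lo alone (368), but 17 against Sca1hi alone. Scaling to array medians ended the calls of Gata1, Hba-a1, Gp1ba, Samd14, Mrvi1, Kit, Spsb4, Thsd1 and Deptor, and quantile normalization those of Aqp1, Kel, Samd14, Mrvi1, Gp1ba and the same 4 lower genes, with no change of direction.

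In the Gr1+ fraction, genes of neutrophil and eosinophil granules were far higher than in both Kit+Gr1- fractions together (3 against 6 arrays). Stfa2l1, a stefin that inhibits cysteine proteases, was higher by 8.02 ± 1.27 on the log2 scale (259-fold, adjusted p = 0.00592), and Ngp, a neutrophil granule protein, by 7.59 ± 1.26 (193-fold, adjusted p = 0.0072). Prg2, the major basic protein of eosinophils, rose by 7.72 ± 1.44 (211-fold, adjusted p = 0.0132) and Epx, the eosinophil peroxidase, by 7.37 ± 1.26 (166-fold, adjusted p = 0.00838). Elane, which encodes neutrophil elastase, rose by 5.97 ± 0.57 (62.7-fold, adjusted p = 0.0011). The iron-binding granule proteins Lcn2 and Ltf rose by 7.50 and 7.06, the antimicrobial peptide gene Camp by 7.31 and the small GTPase Rhou by 7.42. Among stefin relatives Csta1 rose by 6.98, with probes from 2.29 to 6.98, and Cstdc6 rose between Csta1 and Ltf.

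The genes of the gate antigens rose as well. Ly6c1, part of the Gr1 antigen, was higher by 6.75 ± 1.01 (108-fold, adjusted p = 0.00415), and Ly6a, which encodes Sca1, by 4.16 ± 0.44 (17.9-fold, adjusted p = 0.0011), with 4.32 against both within slide 1, 5.43 against Sca1lo within slide 2 and 2.41 against Sca1hi within slide 3. Ly6a thus reached 2.73 ± 0.27 (SD, n = 3) in Gr1+ cells against -0.28 ± 0.38 (SD, n = 3) in Sca1hi cells. Kit did not pass at 0.30 ± 0.26 (adjusted p = 1.00). Spi1, a transcription factor of the myeloid lineage, rose by 1.37 ± 0.25 (adjusted p = 0.0108), whereas Cebpa, its partner in granulocytes, measured 0.98 ± 0.65 and did not pass. Gata1, Gata2, Klf1 and Ddit3 measured 0.07 ± 0.23, 0.02 ± 0.60, -0.86 ± 0.77 and 0.60 ± 0.30 and did not pass.

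Of 38 genes of secondary and tertiary granules and mature neutrophils, 24 rose, Ngp, Lcn2, Camp and Ltf among them, and 14 did not pass, while 34 rose adjusted over the list alone. Their median was 3.20 (camera adjusted p = 1.4e-65, and adjusted p = 0.0110 with an estimated correlation), with 2.79, 3.83 and 3.55 within slides and 3.32 with slide as a block, where adjusted p = 0.104 with an estimated correlation. Of 11 eosinophil genes, 6 rose, among them the ribonuclease gene Ear6 (6.02 ± 0.86) and Prg3 (4.86 ± 0.80), and 5 did not pass, while 8 rose adjusted over the list alone. The eosinophil median was 3.45 (camera adjusted p = 1.5e-18, and adjusted p = 0.00541 with an estimated correlation), with 3.24, 4.97 and 3.85 within slides and 3.97 with the block. Of 37 monocyte and macrophage genes, 13 rose, 1 fell and 23 did not pass, with 21 and 1 adjusted over the list alone. The inhibitory receptor Sirpa (6.89 ± 0.85, probes from 1.24 to 6.89), the chemokines Ccl6 (6.09 ± 1.08) and Ccl3 (4.57 ± 0.88) and the macrophage receptor Adgre1 (4.51 ± 0.85) rose most among them. Their median was 1.70 (camera adjusted p = 2.9e-24, and adjusted p = 0.00541 with an estimated correlation), with 1.54, 1.79 and 2.43 within slides and 1.82 with the block. Of 24 myeloid regulators, 4 rose and 20 did not pass, with 7 rising adjusted over the list alone. Besides Spi1 these were Cebpd (5.06 ± 0.74), a factor of late granulocytes, and the repressors Gfi1 (4.14 ± 0.93) and Bcl6 (1.85 ± 0.31). Their median was 0.81 (camera adjusted p = 3.3e-08, and adjusted p = 0.0117 with an estimated correlation), with 1.01, 1.28 and 1.08 within slides and 0.86 with the block, where adjusted p = 0.104 with an estimated correlation.

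Primary granule genes rose too: 5 of 19, among them Elane, Hp, which encodes haptoglobin (5.98, adjusted p = 0.012), Igsf6 (5.44 ± 0.68) and the lysozyme gene Lyz1 (4.79 ± 1.09), while 14 did not pass, and 14 rose adjusted over the list alone. Their median was 2.37 (camera adjusted p = 2.9e-24, adjusted p = 0.0664 with an estimated correlation), with 2.80, 1.63 and 1.83 within slides. Of 27 cytokine receptor genes, 5 rose, among them the decoy receptor Il1r2 (4.98 ± 0.65), Csf2ra (3.92 ± 0.79), the granulocyte growth factor receptor Csf3r (3.22 ± 0.60) and Tnfrsf1a (2.75 ± 0.58), and 22 did not pass, with 6 rising and 1 falling adjusted over the list alone. Their median was 0.30 (camera adjusted p = 7.1e-08, adjusted p = 0.0567 with an estimated correlation). Of 35 mast cell and basophil genes, 4 rose and 31 did not pass, with 8 rising adjusted over the list alone, at a median of 0.56 (camera adjusted p = 5.7e-07, adjusted p = 0.241 with an estimated correlation). These were the basophil protease Prss34 (5.11 ± 1.06), the receptor Cd200r3 (3.46 ± 0.80), and the cytokine genes Csf1 (3.39 ± 0.71) and Il4 (3.02 ± 0.49). With slide as a block the medians of these 3 lists were 2.16, 0.46 and 0.90. Fry called 6 lists higher and 0 lower in this comparison. With replicate number as a block fry called primary granule genes (fry adjusted p = 0.00527) and cytokine receptors (fry adjusted p = 0.0335) higher. With slide as a block fry called neither (fry adjusted p = 0.0944 and fry adjusted p = 0.0987).

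Ribosome biogenesis genes were lower in Gr1+ cells, with a median of -0.78 over 32 genes (camera adjusted p = 8.0e-16, adjusted p = 0.254 with an estimated correlation) and -0.84, -1.11 and -0.68 within slides. The helicase Ddx21 fell by 1.16 ± 0.24 and 31 did not pass, and 2 fell adjusted over the list alone. DNA replication genes had a median of -0.53 (camera adjusted p = 8.4e-08, adjusted p = 0.510 with an estimated correlation) and mitosis genes of -0.27 (camera adjusted p = 0.00193, adjusted p = 0.585 with an estimated correlation), with no single member passing. With slide as a block the medians of the ribosome, replication and mitosis lists were -0.91, -0.74 and -0.47. Cell cycle exit genes were higher (median 0.48, camera adjusted p = 4.0e-05, adjusted p = 0.259 with an estimated correlation), with the cyclin kinase inhibitor Cdkn2b (2.25 ± 0.44), Gadd45a (1.64 ± 0.27) and Mxi1 (1.26 ± 0.28) rising and 21 not passing. Among immediate early genes the inhibitor Nfkbia (2.09 ± 0.65) and the phosphatase Dusp6 (1.98 ± 0.54) did not pass, though Dusp6 in Gr1+ versus Kit+Gr1- cells passed with replicate number as a block (adjusted p = 0.0482, and 6.43e-05 to 0.988 over all alternatives). The calls of cell cycle exit, glycolysis (0.48), immediate early genes (0.46), endoplasmic reticulum stress (0.16) and p53 targets (0.13) ended with slide as a block, and the last pair turned to -0.04 and -0.07 in the deposited series values. With an estimated correlation these last 4 were at adjusted p = 0.582 to adjusted p = 0.662. The 10 lists that were not called had medians from -0.25 (heat shock) to 0.10 (megakaryocyte and platelet). Oxidative phosphorylation, one of them, was called with slide as a block at -0.29 with the preset correlation, but not with an estimated correlation (adjusted p = 0.765 with an estimated correlation). The cholesterol median was -0.07 while camera placed it above other genes, and the antigen presentation median was 0.01 while camera placed it below.

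Single genes also fell or rose within lists that camera did not call. Of 20 erythroid regulators, Zfpm1, the partner of Gata1, fell by 2.27 ± 0.44, and among red cell genes the carbonic anhydrase Car2 fell by 2.10 ± 0.37 and Kel by 1.91 ± 0.33. Platelet genes split: Gp1ba and Gp5, parts of 1 adhesion receptor, fell by 1.70 ± 0.25 and 1.69 ± 0.31, whereas the matrix and clotting genes Thbs1 and Vwf rose by 2.93 ± 0.54 and 2.83 ± 0.55. Among stem and progenitor genes Ly6a and Gfi1 rose, and Mycn, a growth regulator, fell by 2.49 ± 0.36 and Eng, a receptor of the TGF-beta family, by 1.48 ± 0.28. Of the lymphoid, antigen presentation and interferon genes, the kinase Lck fell by 1.49 ± 0.25, the class II gene H2-Ab1 by 1.59 ± 0.36, Tcf4 by 1.35 ± 0.26 and Usp18 by 2.23 ± 0.31, while the chemokine Cxcl10 rose by 5.30 ± 0.85. The chaperone Hspa1a rose by 1.41 ± 0.32. Within the p53 and stress lists, which camera called with the preset correlation, the survival gene Bcl2a1b rose by 5.07 ± 0.96 and the cystine transporter Slc7a11 by 2.15 ± 0.42. Among genes with a symbol the largest decreases were in Khdc1a, an RNA-binding protein (-3.89 ± 0.45), Vat1l (-3.77 ± 0.70, probes from -3.77 to -0.47), the urea transporter Slc14a1 (-3.43 ± 0.47), the growth factor Fgf3 (-3.18 ± 0.31) and the receptor Cd96 (-3.04 ± 0.42). Hemgn, a nuclear protein of red cell precursors, followed at -3.01 ± 0.38 (probes from -3.01 to -0.64), then Podxl, a surface sialomucin (-2.99 ± 0.34), Grtp1 (-2.98 ± 0.41), Ccdc102a (-2.94 ± 0.39) and Itm2a (-2.87 ± 0.48).

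Limma called 626 genes here, 434 higher and 192 lower, of which 336 and 130 had a symbol, and the higher genes made up 69.3% of calls, or 85.8% with array medians (169 higher, 28 lower). All 626 had the same sign within slides 1, 2 and 3, which the choice of these genes on the same arrays largely fixes. With slide as a block 745 genes were called (462 higher, 283 lower). Lyz1, Csf2ra, Tnfrsf1a, Cdkn2b, Mxi1, Ccl3, Adgre1, Prss34, Cd200r3 and Csf1 were not called there. Without the 4 compressed arrays 1998 genes were called (1096 higher, 902 lower), 622 of the 626 among them. The lowest count with 1 array left out was 108, without Gr1+ replicate 2, and leaving out unfractionated replicate 1 gave 1344.

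**Figure D2:**
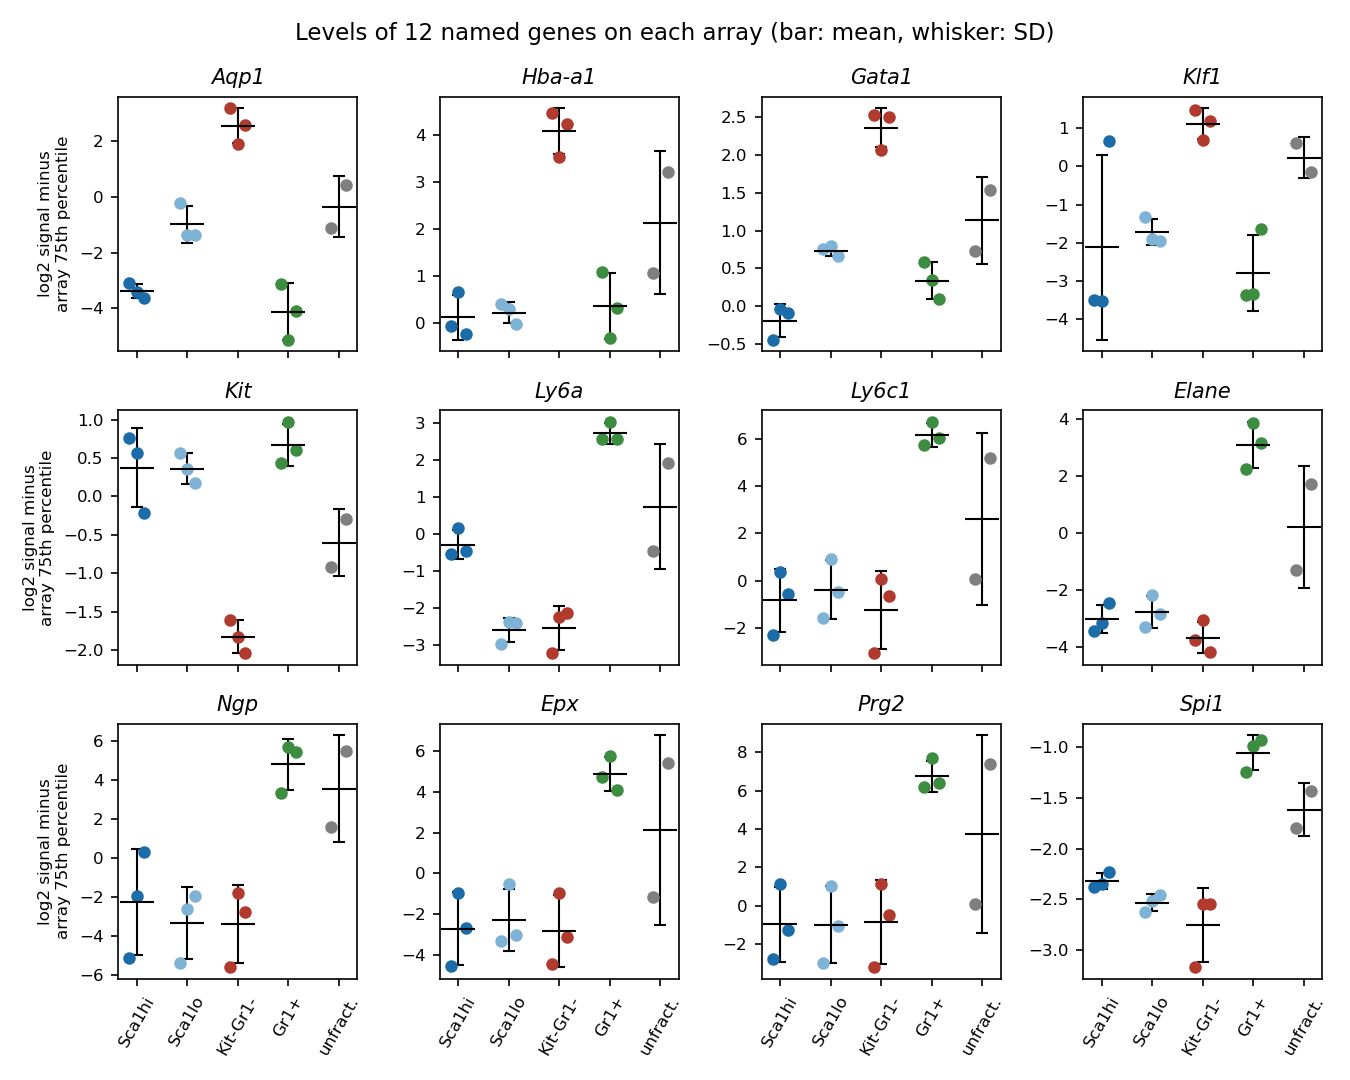
Signal of 12 genes on each array (log2, relative to the array's 75th percentile) in the 5 groups: dots are arrays, bars group means and whiskers SDs. Aqp1 reached 2.56 ± 0.63 in Kit-Gr1- cells and Epx 4.86 ± 0.83 in Gr1+ cells, and both unfractionated arrays lay far apart for Epx and Prg2.

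Set directly against each other, the Kit-Gr1- and Gr1+ fractions (3 against 3 arrays) differed by red cell and platelet genes on one side and granule genes on the other. Aqp1 was higher in Kit-Gr1- cells by 6.67 ± 0.55 (102-fold, adjusted p = 0.000222) and Kel by 5.39 ± 0.38 (42.0-fold, adjusted p = 8.5e-05). Tmod1, which caps the actin filaments of the red cell skeleton, was not well above background on any of the 3 Gr1+ arrays. Its fitted difference was 6.28 ± 0.84 (probes from 3.18 to 6.28), and against the background it was at least 39.6-fold higher. Gata1 was higher by 2.03 ± 0.26, Klf1 by 3.90 ± 0.89 (adjusted p = 0.0486), Zfpm1 by 3.58 ± 0.51 and the repressor Gfi1b by 2.21 ± 0.46. Gp1ba, Gp5 and Gp9, which form the platelet receptor for von Willebrand factor, were higher by 3.66 ± 0.29, 3.31 ± 0.36 and 2.78 ± 0.41. Art4 (4.33 ± 0.47), Samd14 (4.32 ± 0.41), Slc14a1 (4.19 ± 0.54), Mrvi1 (4.04 ± 0.37), Cd96 (3.97 ± 0.48) and Spdye4b (4.36 ± 0.60), a cell cycle regulator of the Speedy family, were also among the largest increases.

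On the Gr1+ side Rhou was lower in Kit-Gr1- cells at -8.68 ± 1.37 (adjusted p = 0.00591), Ngp at -8.18 ± 1.45 (adjusted p = 0.0118), Epx at -7.71 ± 1.45 (adjusted p = 0.0172) and Prg2 at -7.59 ± 1.66 (adjusted p = 0.0394). Lcn2 (-8.08 ± 1.54), Camp (-7.97 ± 1.43), Ly6c1 (-7.38 ± 1.16), Ltf (-7.37 ± 1.44), the chitinase-like gene Chil1 (-7.31 ± 1.15) and the surface enzyme Bst1 (-7.25 ± 1.39) followed. Elane was lower at -6.75 ± 0.66, Ly6a at -5.26 ± 0.50, Kit at -2.50 ± 0.30 and Spi1 at -1.70 ± 0.29. Within slides 1, 2 and 3 Kit measured -2.04, -2.81 and -2.65. Cebpa (-1.05 ± 0.75), Gata2 (0.78 ± 0.69) and Ddit3 (-0.22 ± 0.34) did not pass. For 8806 of the tested genes (27.1%) all 3 arrays of one fraction lay above all 3 of the other, against 10% by chance.

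Of 48 genes for haemoglobin, haem and the red cell membrane, 10 were higher in Kit-Gr1- cells and 38 did not pass, and 14 were higher adjusted over the list alone. Their median was 0.67 (camera adjusted p = 9.3e-20, and adjusted p = 0.00287 with an estimated correlation), with 1.07, 0.64 and 0.48 within slides. Of 20 erythroid regulators, 5 were higher and 15 did not pass, with 6 adjusted over the list alone, at a median of 0.54 (camera adjusted p = 5.05e-10, and adjusted p = 0.00627 with an estimated correlation) and 0.72, 0.44 and 0.47 within slides. Of 26 megakaryocyte and platelet genes, 3 were higher and 23 did not pass, with 4 higher and 1 lower adjusted over the list alone, at a median of 0.70 (camera adjusted p = 2.2e-08, and adjusted p = 0.0263 with an estimated correlation) and 0.50, 0.59 and 0.64 within slides. Secondary granule genes were lower, 21 of 38 (32 adjusted over the list alone), at a median of -3.71 (camera adjusted p = 4.2e-47, and adjusted p = 0.0188 with an estimated correlation) and -2.90, -4.06 and -4.12 within slides. With slide as a block the secondary granule call ended at adjusted p = 0.0615 with an estimated correlation. Eosinophil genes were lower, 6 of 11 (9 adjusted over the list alone), at a median of -4.32 (camera adjusted p = 6.0e-18, and adjusted p = 0.00357 with an estimated correlation) and -2.74, -4.94 and -4.54 within slides. Monocyte genes were mostly lower, with 7 lower, 1 higher and 29 not passing (17 and 1 adjusted over the list alone), at a median of -1.75 (camera adjusted p = 8.1e-17, and adjusted p = 0.0103 with an estimated correlation) and -1.65, -1.61 and -1.87 within slides. Sirpa (-7.05 ± 0.98), the endotoxin receptor Cd14 (-4.26 ± 0.81), Tlr7 (-3.74 ± 0.79) and Ctss (-2.98 ± 0.62) were among them. Of 24 myeloid regulators, 4 were lower and 20 did not pass (7 adjusted over the list alone), at a median of -1.03 (camera adjusted p = 1.6e-06, and adjusted p = 0.0193 with an estimated correlation) and -0.81, -0.82 and -1.08 within slides.

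A further 7 lists were called by camera with the preset correlation alone. Fry called 3 lists higher and 6 lower in this comparison. With replicate number as a block fry called primary granule genes (fry adjusted p = 0.00654) and cytokine receptors (fry adjusted p = 0.0211) lower. With slide as a block these were at fry adjusted p = 0.0545 and fry adjusted p = 0.0499. Primary granule genes had a median of -2.18 (adjusted p = 0.146 with an estimated correlation), with 4 of 19 lower (Elane, Hp, Igsf6 and Prtn3) and 10 adjusted over the list alone, and cytokine receptors had a median of -0.48 (adjusted p = 0.146 with an estimated correlation). Of 27 receptors, Il1r2 (-5.71 ± 0.75), Csf3r (-5.09 ± 0.69), Tnfrsf1a (-3.93 ± 0.67) and Kit were lower and Epor (2.70 ± 0.35) higher. Ribosome biogenesis genes were higher in Kit-Gr1- cells, with a median of 0.80 (camera adjusted p = 6.7e-19, adjusted p = 0.146 with an estimated correlation) and 0.70, 0.97 and 0.73 within slides, and 2 of 32 were higher adjusted over the list alone. DNA replication (0.50), oxidative phosphorylation (0.38), cholesterol synthesis (0.26) and mitosis (0.24) were also higher, at adjusted p = 0.526 to adjusted p = 0.728 with an estimated correlation, and mitosis measured -0.01 within slide 3. The other 11 lists were not called by camera. Among them the interferon and antigen presentation medians were -0.22 and -0.38 while camera placed both above other genes, and the stress and p53 medians were 0.06 and 0.10 with means of -0.06 and -0.15. The stem and progenitor list had a median of -0.26. Fry called this list lower with replicate number as a block (fry adjusted p = 0.0277), but not with slide as a block (fry adjusted p = 0.403). In this list Slamf1 (3.11 ± 0.49) and Mycn (2.54 ± 0.41) were higher, while Ly6a and Kit, also members, were lower as given above. Usp18 (2.18 ± 0.36) and Ccl17 (1.71 ± 0.30) were higher, and Cxcl10 (-6.30 ± 0.98), Bcl2a1b (-6.06 ± 1.11) and Hspa1a (-1.70 ± 0.37) lower, as single members of lists that were not called.

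Limma called 495 genes between these fractions, 178 higher in Kit-Gr1- cells and 317 higher in Gr1+ cells, of which 128 and 242 had a symbol. The median of all genes was -0.23, or 0.08 with array medians. Slides 1, 2 and 3 each held 1 array of both fractions, so that list medians with slide as a block equal those given. All 495 genes had the same sign within each of these slides, which their choice on the same arrays largely fixes. With the block 655 genes were called (257 and 398), where Klf1, Cd14 and Ear6 were among the named genes not called. Without the 4 compressed arrays 1801 genes were called (804 and 997), the 495 among them. The lowest count with 1 array left out was 148, without Gr1+ replicate 2, and leaving out unfractionated replicate 1 gave 1244.

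**Figure D3:**
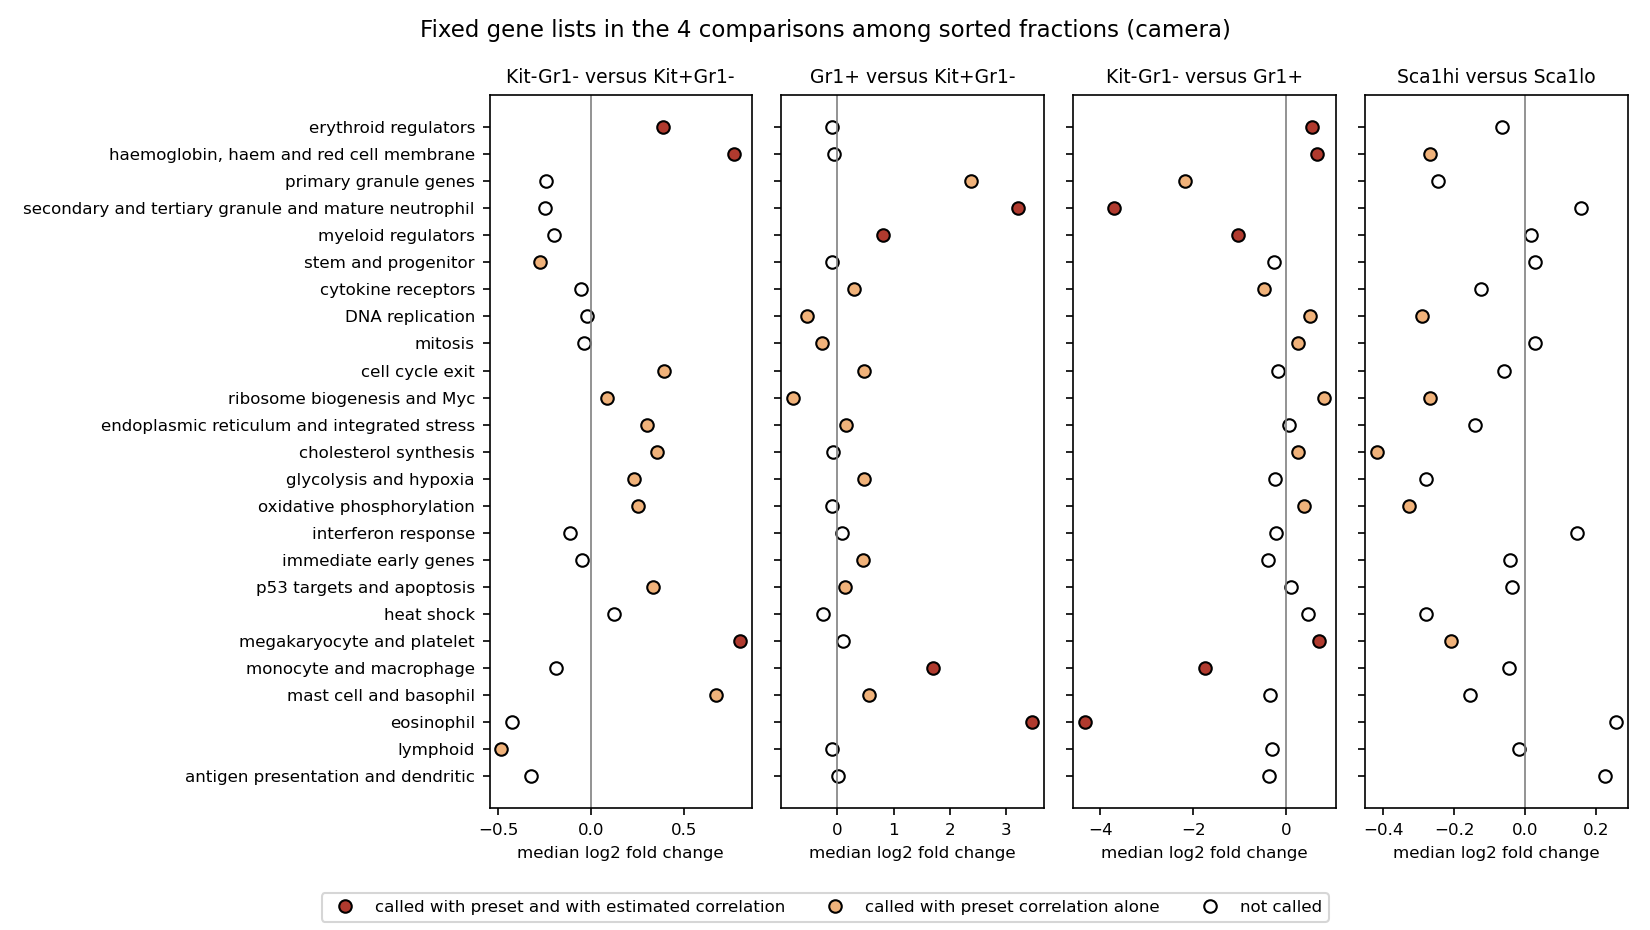
Median log2 fold change (x axis) of 25 gene lists (y axis) in the 4 comparisons of sorted fractions: red points were called by camera with the preset and with the estimated correlation, orange points with the preset alone and white points not at all. The eosinophil and secondary granule lists lay at 3.45 and 3.20 in Gr1+ against Kit+Gr1- cells, and the stem and progenitor median in Kit-Gr1- against Kit+Gr1- cells, -0.28, turned to 0.04 with array medians.

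Within Kit+Gr1- cells no gene passed between Sca1hi and Sca1lo (3 against 3 arrays). Ly6a, the gene of the sorting marker, was higher in Sca1hi cells by 2.31 ± 0.50 on the log2 scale (4.94-fold, adjusted p = 1.00), with all 3 Sca1hi arrays above all 3 Sca1lo arrays. It measured 2.42 and 1.95 within slides 1 and 4, the slides that held both groups, and 2.10 ± 0.48 with slide as a block. Aqp1 was lower in Sca1hi cells at -2.40 ± 0.55 (5.26-fold), Kel at -1.67 ± 0.38 and Gata1 at -0.93 ± 0.26, each with all 3 Sca1hi arrays below all 3 Sca1lo arrays, and none passed (adjusted p = 1.00). Within slides 1 and 4 Aqp1 measured -2.88 and -2.26, Kel -1.99 and -1.79, and Gata1 -1.20 and -0.75. Gata1 thus stood at -0.19 ± 0.22 in Sca1hi, 0.73 ± 0.07 in Sca1lo and 2.36 ± 0.26 in Kit-Gr1- cells (SD, n = 3 each). Klf1 measured -0.39 ± 0.89 but -2.17 within slide 1 and 2.63 within slide 4. Kit (0.01 ± 0.30), Spi1 (0.21 ± 0.29), Gata2 (-0.15 ± 0.69), Cebpa (-0.26 ± 0.75), Ddit3 (0.17 ± 0.34), Ly6c1 (-0.45 ± 1.16) and Epor (-0.64 ± 0.35) did not pass either.

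Camera with the preset correlation placed 6 lists lower in Sca1hi cells and fry called none. They were cholesterol synthesis (median -0.42), oxidative phosphorylation (-0.33), DNA replication (-0.29), red cell genes (-0.27), ribosome biogenesis (-0.27) and platelet genes (-0.21). Each lost its call, at adjusted p = 0.138 (red cell genes) to adjusted p = 0.710 with an estimated correlation, and without the 4 compressed arrays the DNA replication, ribosome and platelet medians were -0.09, -0.05 and -0.06 and not called. Within slides 1 and 4 the medians were -0.20 and -0.80 for cholesterol synthesis and -0.10 and -0.23 for red cell genes, of which 2 were lower adjusted over the list alone. The other 19 lists were not called, and for 5 of them, lymphoid and monocyte genes among them, the median was negative while camera placed the list above other genes. With slide as a block camera with the preset correlation also placed glycolysis (-0.60), heat shock (-0.59), primary granule genes (-0.50), stress of the endoplasmic reticulum (-0.46) and erythroid regulators (-0.33) lower and eosinophil genes (0.37) higher. None of these 6 was called with an estimated correlation, at adjusted p = 0.349 to adjusted p = 0.827 with an estimated correlation. With replicate number as a block camera with the preset correlation also called glycolysis and hypoxia in Sca1hi versus Sca1lo (-0.28, adjusted p = 0.0137, and 5.98e-11 to 0.967 over all alternatives) and interferon response in Sca1hi versus Sca1lo (0.15, adjusted p = 0.0347, and 0.000119 to 0.983). With an estimated correlation under that block neither was called, at adjusted p = 0.802 and adjusted p = 0.516.

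The genes that separate Kit-Gr1- from Gr1+ cells were then followed between Sca1hi and Sca1lo cells, whose arrays entered the choice of these genes through the pooled spread, the filter and the choice of probe. Of the 178 genes higher in Kit-Gr1- cells, 141 (79.2%) were higher in Sca1lo than in Sca1hi cells, against 51.3% of all genes. Their median difference was -0.19 and their mean -0.27 (camera adjusted p = 1.87e-15, adjusted p = 0.237 with an estimated correlation). Fry, which takes the correlation between genes from the data, gave an adjusted p of 0.570, or 0.00488 with slide as a block at a median of -0.32, and between 0.167 and 0.892 under the other alternatives. By replicate number the medians were -0.18, 0.05 and -0.44, and without Sca1hi replicate 3, a compressed array, the median was -0.02. The 317 genes higher in Gr1+ cells had a median of 0.15 (camera adjusted p = 9.99e-09, adjusted p = 0.322 with an estimated correlation).

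Limma called 0 of 32476 genes between Sca1hi and Sca1lo cells, with 75 at an unadjusted p under 0.05 against 1624 that chance gives. For 953 genes (2.93%) the arrays did not overlap, against 10% by chance. Counts this far below chance mark a test that misses differences, so 0 calls do not show that the fractions are alike. Same-numbered arrays of both groups deviated together (correlations of 0.66, 0.68 and 0.82), to which the compressed replicate 3 arrays contribute. A fit without a block leaves such deviation in the spread, yet with replicate number as a block the count also stayed far below chance. The unfractionated pair enters the pooled spread as well. Without unfractionated replicate 1 there were 290 at an unadjusted p under 0.05. With slide as a block limma called 0 (253 at an unadjusted p under 0.05), and without the 4 compressed arrays 0 (437). With array weights, which lower the part of scattered arrays, it called 93 (81 higher and 12 lower in Sca1hi). Among them were Ly6a (2.24), Aqp1 (-2.44), Kel (-1.76), Gata1 (-1.16) and Klf1 (-1.82), which did not pass in the main fit. The Sca1hi arrays then had weights of 5.60, 0.471 and 0.170, so these calls rest mostly on Sca1hi replicate 1.

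The means of the 2 unfractionated arrays lay between the sorted fractions for the gate markers, but no gene passed. Replicate 1 had compressed signals and correlated at 0.509 with replicate 2 across genes, so these means do not place unfractionated cells. Against Kit+Gr1- cells, Ly6a was 2.18 ± 0.50 higher (adjusted p = 0.165), Ly6c1 3.21 ± 1.16 (adjusted p = 0.218), Klf1 2.15 ± 0.89, Gata1 0.86 ± 0.26 (adjusted p = 0.200) and Kit -0.97 ± 0.30 (adjusted p = 0.201). Against Kit-Gr1- cells Ly6a measured 3.28 ± 0.56, Kit 1.23 ± 0.33 and Gata1 -1.23 ± 0.29. Against Gr1+ cells Ly6a measured -1.98 ± 0.56, Ly6c1 -3.54 ± 1.30 and Klf1 3.01 ± 0.99. The pair of arrays differed widely for granule genes, with SDs of 4.66 for Epx and 5.14 for Prg2, against 0.83 and 0.80 in Gr1+ cells. Limma called 0 genes in each of the 3 comparisons, with 5594, 6056 and 2657 at an unadjusted p under 0.05 against Kit+Gr1-, Kit-Gr1- and Gr1+ cells. Without unfractionated replicate 1 it called 315, 180 and 1 genes, with the lone remaining array assumed to vary like the other groups. With slide as a block it called 90, 47 and 4, and without the 4 compressed arrays 510, 264 and 2.

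Few genes changed against Kit+Gr1- cells in both the Kit-Gr1- and the Gr1+ fraction, though more than independent lists of these sizes would share. There were 1 higher in both (0.227 expected), 1 lower in both (0.0236 expected) and 4 opposite (0.154 expected). Both comparisons share the Kit+Gr1- arrays, so the expected counts are no test. Thsd1 fell in both, at -1.83 and -2.29, and the transcript AK007931, named after its values were seen, rose in both. Kel, Gp1ba, Samd14 and BC031139, the last also named after its values were seen, rose in Kit-Gr1- cells and fell in Gr1+ cells. The log2 fold changes of both comparisons correlated at 0.05 across genes, which are not independent replicates, beside 0.525 in 20 simulations with no effect and the same shared arrays. Those took the arrays' deviations as independent, while Gr1+ and Kit+Gr1- arrays of equal number deviated together. With equal numbers kept together 20 simulations gave 0.302. The covariance was 0.02, beside 0.132 and 0.0413. Since the simulated value depends on how the arrays deviate together, no departure from it is claimed. With split controls the correlation was -0.24 (Kit-Gr1- against Sca1hi, Gr1+ against Sca1lo) and 0.16 the other way round. The 6 shared genes became 55 without the 4 compressed arrays and 0 without Kit-Gr1- replicate 1 or replicate 3.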

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

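The tests of missing cells or transcripts and of a share of Gr1+ cells were chosen after the result was seen, while those of a constant background and of a background under dim probes were not.

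The negative control spots, 153 per array, carry no mouse sequence and were used in no comparison. They stood out because their median unprocessed signal was raised on 4 arrays, at 66 scanner units on Sca1hi replicate 3, 57 on Sca1lo replicate 3, 47 on Gr1+ replicate 3 and 515 on unfractionated replicate 1. On the other 10 arrays it lay between 32 and 35. These are the same 4 arrays whose log2 signals were compressed.

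On unfractionated replicate 1 the signals were high and compressed, with an interquartile range of 1.78 on the log2 scale and a spike-in slope of 0.667, against slopes of 0.906 to 0.990 on the other 13 arrays. A constant background added to every spot would leave dim probes alike, but the 299 probes that were below background on all other arrays spread there with an interquartile range of 2.48, around a median of 349 against at most 14.2 elsewhere. These are processed signals, from which a background had already been subtracted, so this range does not by itself decide against a constant background. Cells or transcripts missing from the sorted fractions would leave the negative controls as they were, but these stood at 7.80 times the highest median of any other array. A constant background thus stays open in part. So does a technical step between labelling and scanning that may raise each probe by its own amount, which was not tested.

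Granule genes were present on some arrays of the other fractions: in Sca1hi, Sca1lo and Kit-Gr1- replicate 2 and in Kit-Gr1- replicate 3, a set of 10 abundant Gr1+ genes (Epx, Prg2, Ngp, Lcn2, Mmp8, Stfa2l1, Sirpa, S100a8, S100a9 and 1 unnamed transcript), chosen as far lower on the replicate 1 arrays of these fractions, stood above the replicate 1 array by a median of 3.73, 3.11, 4.05 and 2.63 on the log2 scale. Since the choice of genes used the replicate 1 arrays, it partly fixes this rise. A background that raises all dim probes is argued against, since genes of matched level did not rise on these arrays, with medians of -0.72, -0.22, -0.20 and -0.52 and a highest ratio of -0.0497 to the rise of the granule genes. A small share of Gr1+ cells or of their RNA stays as a candidate explanation: it needs like percentages of the Gr1+ level, and the upper and lower quartiles of the 10 genes differed by a factor of at most 1.63 on each array. Not every gene kept to 1 share, since the highest and lowest differed by factors of 4.51, 4.99, 4.75 and 8.71. S100a9 was highest on each array, at 5.24%, 3.59%, 6.10% and 2.66%, Mmp8 reached 4.42% on Kit-Gr1- replicate 2 and Epx was lowest on Kit-Gr1- replicate 3 at 0.306%. A common share thus leaves these values unexplained, and their cause was not tested. The median shares were 1.47%, 1.38%, 1.85% and 0.709%, against 0.106% to 0.127% on the replicate 1 arrays. The Gr1 gate is meant to exclude such cells, but how fully it did so was not measured here. No biological explanation was tested.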

How the results depend on the processing

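The fits without the 4 compressed arrays and without unfractionated replicate 1 as a doubted array were the tests chosen after the result was seen. Where a value moved, the cause was not tested unless the construction of the setting names it.

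For the called named genes, directions held more widely than calls. Of 133 calls of named genes, between 61 (array medians) and 133 held per setting and none turned. With series matrix values 88 held, and with 1 array left out 58 (without Gr1+ replicate 2) to 133. Over single genes and lists, 7944 alternative values kept their side of the threshold, 299 newly passed and 557 no longer passed. A further 17, which passed in the main fit or in the alternative, turned. Values that passed in neither were counted among the 7944 whatever their direction. The secondary granule list in Kit-Gr1- against Kit+Gr1- cells, placed below other genes with slide as a block, is an example. The 48 calls of gene lists ranged from 42 to 67. Between Sca1hi and Sca1lo cells limma called 0 genes under every setting except array weights.

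With quantile normalization Kit-Gr1- against Kit+Gr1- cells had 11 calls in place of 21, unfractionated against Kit+Gr1- cells 209 in place of 0, and the shared changes 0 in place of 6. With array medians Gr1+ against Kit+Gr1- cells had 197 in place of 626, Kit-Gr1- against Gr1+ cells 188 in place of 495, and the shared changes 1. Normexp background gave 3 shared changes and no trend in eBayes 2. With the groups compared alone in the fit, which leaves out the spread of unfractionated cells, the first 3 comparisons had 80, 1229 and 1523 calls and 32 shared changes. With array weights they had 763, 2189 and 1929, Sca1hi against Sca1lo 93, and 328 changes were shared. With series matrix values Kit-Gr1- against Kit+Gr1- cells had 13, and unfractionated cells against Kit+Gr1-, Kit-Gr1- and Gr1+ cells 189, 120 and 8. Against Sca1lo alone, with fewer arrays, limma called 0 genes for Kit-Gr1- (368 at an unadjusted p under 0.05) and 402 for Gr1+ cells, and against Sca1hi alone 320 for Gr1+ cells.

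Slide as a fixed block gave 90, 47 and 4 calls for unfractionated cells, and the Kit-Gr1- genes between Sca1hi and Sca1lo passed fry at a median of -0.32. Slide as a random block gave 31 and 3 calls for unfractionated against Kit-Gr1- and Gr1+ cells and 10 shared changes. Replicate number as a block gave 116 and 132 calls for unfractionated against Kit+Gr1- and Kit-Gr1- cells. In the comparisons whose equal-numbered arrays deviated together, Gr1+ against Kit+Gr1- cells had 774 calls and Sca1hi against Sca1lo 0 (120 at an unadjusted p under 0.05). Among named genes and gene lists only Dusp6 and the glycolysis and interferon lists changed their call there. Whether these numbers pair the arrays is not known. With Kit-Gr1- cells equal numbers did not deviate together (correlations of 0.12, 0.04 and -0.23 with Sca1hi, 0.19, 0.14 and -0.14 with Sca1lo, and 0.19, 0.11 and 0.04 with Gr1+), not every array correlated best with its own number, and the block gave 27 and 658 calls.

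Without the 4 compressed arrays the counts were 130, 1998 and 1801 for the first 3 comparisons, 510, 264 and 2 for unfractionated cells, and 55 shared changes.

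The 17 values counted as turned were lists that camera called in the main fit or the alternative and placed on the other side of other genes. Among them the median itself changed sign only for ribosome biogenesis in Kit-Gr1- against Kit+Gr1- cells and for cell cycle exit between Sca1hi and Sca1lo cells, and a median that changed sign while camera's side held is not counted. In Kit-Gr1- against Kit+Gr1- cells, with quantile normalization, slide as a fixed block, series matrix values and without the 4 compressed arrays, DNA replication measured -0.21, -0.24, -0.26 and -0.19, mitosis -0.21, -0.23, -0.28 and -0.20, and ribosome biogenesis -0.11, -0.074, -0.15 and -0.051. Camera with the preset correlation called DNA replication and mitosis lower in all 4 settings and ribosome biogenesis with quantile normalization alone. Between Sca1hi and Sca1lo cells 5 lists turned without Sca1hi replicate 3. With 1 array left out, from without Sca1hi replicate 2 to without replicate 3, DNA replication ranged from -0.53 to -0.00363, cell cycle exit from -0.17 to 0.072, ribosome biogenesis from -0.45 to -0.033, stress of the endoplasmic reticulum from -0.33 to -0.049 and oxidative phosphorylation from -0.56 to -0.077.

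With 1 array left out, Kit-Gr1- against Kit+Gr1- cells ranged from 0 (without Kit-Gr1- replicate 1 or 3, with 434 and 407 at an unadjusted p under 0.05) to 106 (without unfractionated replicate 1). Gr1+ against Kit+Gr1- cells ranged from 108 (without Gr1+ replicate 2) to 1344 (without unfractionated replicate 1), with 414 and 389 without replicate 1 of Sca1hi and Sca1lo and 412 and 342 without Gr1+ replicates 1 and 3. Kit-Gr1- against Gr1+ cells ranged from 148 (without Gr1+ replicate 2) to 1244 (without unfractionated replicate 1), with 174, 303 and 197 without Kit-Gr1- replicates 1, 2 and 3 and 270 without Gr1+ replicate 3. Unfractionated cells ranged from 0 to 18957, 22460 and 15391 against Kit+Gr1-, Kit-Gr1- and Gr1+ cells, the highest without unfractionated replicate 2, when the compressed array stood alone and was assumed to vary like the other groups. They were 315, 180 and 1 without unfractionated replicate 1, and 216 against Kit+Gr1- cells without Sca1hi replicate 3. Shared changes ranged from 0 (without Kit-Gr1- replicate 1 or 3) to 43 (without unfractionated replicate 1), lists from 46 to 58, and the Kit-Gr1- genes between Sca1hi and Sca1lo from -0.41 (without Gr1+ replicate 2) to -0.02 (without Sca1hi replicate 3).

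Gene lists with slide as a random block were not run, since camera takes no random block. With probes above background on all arrays, genes under that level drop out, and the 121 named calls that remained all held. Signal over background limits what dim genes show: on Sca1hi replicate 2, 79.5% of spots were well above it.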

Other observations

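The tests of the genes lower in Sca1hi cells were chosen after the result was seen, and the counts of other splits were not.

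Of the mast cell and basophil genes, which as a list were not called between Kit-Gr1- and Gr1+ cells (median -0.36, 13 genes higher and 22 lower), 3 named ones had their highest means in Gr1+ cells. The protease gene Mcpt8 stood at 2.27 ± 1.02 (SD, n = 3) in Sca1hi, 2.55 ± 1.03 in Sca1lo, 4.95 ± 0.94 in Kit-Gr1- and 6.08 ± 0.63 in Gr1+ cells, on the log2 scale relative to the array's 75th percentile. The receptor gene Cd200r3 stood at 0.59 ± 0.82, 0.10 ± 0.74, 2.53 ± 0.70 and 3.80 ± 0.55, and the cytokine gene Il4 at -1.13 ± 0.54, -1.40 ± 0.33, 0.44 ± 0.72 and 1.75 ± 0.62. Gata2, which both lineages and progenitors use, varied less, from 3.86 ± 0.56 in Sca1hi to 4.74 ± 0.46 in Kit-Gr1- cells. Platelet genes took different courses: Gp9 was highest in Kit-Gr1- cells (3.01 ± 0.46 against 0.23 ± 0.24 in Gr1+ cells), while Vwf stood at 2.02 ± 0.91 in Kit-Gr1- and 3.06 ± 0.91 in Gr1+ cells, against 0.41 ± 0.38 in Sca1hi cells. Mpo, the myeloperoxidase gene, had a high mean signal in every fraction, from 4.10 ± 1.57 in Kit-Gr1- to 9.12 ± 0.11 in Gr1+ cells. How far a small share of Gr1+ RNA, the candidate named above for granule genes, adds to the Kit-Gr1- value was not tested.

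Across genes, which are not independent replicates, unfractionated replicate 2 correlated best with Gr1+ replicate 2 (r = 0.984), and unfractionated replicate 1 reached 0.811 with Sca1hi replicate 3, 0.728 with Gr1+ replicate 3 and 0.509 with unfractionated replicate 2.

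The 17 genes called higher in Kit-Gr1- than in Kit+Gr1- cells were all lower in Sca1hi than in Sca1lo cells, with a median difference of -0.70, and for 11 of them all Sca1lo arrays lay above all Sca1hi arrays. The same arrays entered the choice of these genes, as the comparator and in the pooled spread, which favours genes of low spread, so no p is given. Same-numbered arrays gave medians of -1.20 on slide 1, -0.83 across slides and -0.44 on slide 4, and slide as a block gave -0.77. Compressed signals on the replicate 3 arrays are argued against, since the median without them was -1.01. A share of Kit-Gr1- cells with that fraction's mean profile in the Sca1lo fraction stays open. The Kit gate is meant to exclude such cells, but how fully it did so was not measured here. The median gene would need a share of 11.9%, and the quartiles over the 17 genes, 8.44% and 16.3%, differed by a factor of 1.93. Against it, the 2 most abundant of these genes fell short of the level it gives, Hba-a1 by 1.33 and an unnamed transcript by 0.672 on the log2 scale. Their own shares were 0.00202% and 2.26%, but a pair of genes does not decide for the set. A difference between the Sca1hi and Sca1lo fractions themselves stays open too and was not tested further.

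Other splits of the same arrays into groups of the same sizes were set beside each count. They were fitted on those arrays alone as 2 groups, with the genes and probes of the main fit. The setting with the groups compared alone chose genes and probes anew, so its counts differ from those of the real splits. For Kit-Gr1- against Kit+Gr1- cells 1 of the 84 splits, the real one with 78 genes, gave as many, a share under 0.05. Such a share makes chance less likely as the source of that count but does not exclude it. The splits also treat all arrays as alike, while slides and compressed signals set some apart. The highest other split, with 22, put the 3 replicate 1 arrays of slide 1 together. For Gr1+ against Kit+Gr1- cells 2 of the 84 splits gave as many as the real 1264, a share under 0.05 with the same limits. The other, with 8826 genes, put the 3 replicate 3 arrays with compressed signals together, which points to a structure of the samples. Among the 27 splits with 1 array of each number in the smaller group, the highest other count was 0. For Kit-Gr1- against Gr1+ cells 1 of the 10 splits gave as many as the real 1508, with 0 as the highest other, and for Sca1hi against Sca1lo cells 10 of the 10 splits gave 0. In the last pair of comparisons the splits are too few for a share under 0.05.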
